A study of Mus musculus with 8 samples.

How the data were processed

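RNA sequencing values were used from hair matrix keratinocytes of mice in 4 groups: wild type (WT) and Tet2/3 double knockout (DKO), each untreated and after 5-aza. Each group had 2 libraries. Per the labels, cells were sorted by flow cytometry at postnatal day 4.5, and 50 µg of 5-aza was injected under the skin at postnatal day 2.5. The labels name 2 different RNA and library kits, one for messenger RNA and one for total RNA depleted of ribosomal RNA, and do not tie either to a group. They do not give the markers of the sort or the strand setting of the counting. They also do not say whether the libraries came from separate animals, so the p-value of a single gene measures only the spread between these libraries.

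The submitters' processing notes name Trim Galore, STAR, HTSeq and DESeq2 and the builds GRCm38 and mm10, without versions. The authors deposited 2 tables, one for each comparison of DKO with WT. The library columns hold FPKM, a unit the headers do not name; value times length is a whole multiple of 1 step within 0.001 reads for every gene, so the authors' values are FPKM scaled to each library's total. The deposited mean column is a signal value, the mean of reads divided by 1 size factor per library. The deposited fold changes and their standard errors are log2 values of WT over DKO per the file headers and the library columns, and their sign was reversed here. The deposited statistic is a score from the authors' DESeq2 test. The deposited p-value columns (p_value) hold the p and adjusted p of the authors' DESeq2 test. The deposited length column, of unit other, is the gene length in bases behind the FPKM.

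The untreated table lists 29647 genes with FPKM and 0 mitochondrial genes. The 5-aza table lists 29246 genes with FPKM, 25 of them mitochondrial, and 376 gene identifiers without a name or FPKM. The tables share 26200 genes. Listed genes held 55.8% to 62.0% of the library total in the untreated libraries and 38.4% to 42.4% in the 5-aza libraries. Because the tables were processed differently, the planned tests of 5-aza against untreated within WT and within DKO were not run. The interaction was run, since a difference between tables that scales both genotypes alike largely cancels in it for genes of high FPKM. In genes of low FPKM such a difference does not fully cancel, because a constant was added to each value before the logarithm. A difference that acts on WT and DKO differently does not cancel at any level.

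A count model had been planned, with limma on log2 of the value plus 1 as the fallback if the columns were not counts. The columns are FPKM, so the fallback was used, and edgeR and DESeq2 were not run here. Values were log2(FPKM + 1), fitted with limma 3.58.1 in R 4.3.3 with a variance trend, and p-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05 on the adjusted p. The low-value filter was the rule of the planned count filter: at least 10 reads at the median library size in at least 2 libraries and at least 15 reads in total, from whole reads recovered from FPKM and length. The fallback had fixed neither a filter nor a trend; both were settled after exploratory fits with several filters, with voom and without a filter had been seen, and the counts under those settings are given with the results or in the closing section. Scaling was that of the deposited values. Self-test data with 200 changed genes were simulated 5 times for each comparison. The test called 94.2% of 4-fold and 36.6% of 2-fold changes in simulated untreated data, with a mean of 6.8 false calls, and 95% and 46.6% in simulated 5-aza data, with 5.4 false calls. The simulated dispersion varied between genes, scaled from 0.00416 and 0.00424. The changed genes were drawn only among genes above a minimum mean of reads. The percentages hold for that spread and for such genes alone.

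The comparisons were DKO with WT in untreated libraries, DKO with WT in 5-aza libraries, and the interaction of genotype and 5-aza over 8 libraries. Before the data were examined, 31 gene lists were fixed, 17 of biology, 9 of other cell types and 5 of RNA and sample quality. They covered hair shaft keratins, inner root sheath genes, keratin-associated proteins, hair matrix and shaft regulators, basal and outer root sheath genes, interfollicular differentiation, Wnt, BMP, Hedgehog and Notch pathways, proliferation, p53 targets, interferon-stimulated genes, methylation-silenced germline genes, imprinted genes, DNA methylation machinery and Hox genes. The other lists were markers of melanocytes, dermal papilla, fibroblasts, endothelial and mural cells, immune cells, erythroid cells, adipocytes, skeletal muscle, and Schwann and Merkel cells, with genes of dissociation stress, mitochondria, ribosomal proteins, histones and sex linkage. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and fry beside it. Camera compares the members of a list with the other genes, so its p-values do not measure the spread between libraries alone. Members were also adjusted over the list alone. The mitochondrial list had no genes in the untreated table, and the erythroid list had too few genes past the filter in the 5-aza table, so neither was tested there.

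The rule for named genes, also fixed before the data were examined, took Tet2 and Tet3, the 6 higher and 6 lower genes with the smallest p past the threshold, up to 2 members of each biology list past the threshold, and the most abundant member of each other list. For the 6 higher and 6 lower it required both DKO libraries on the same side of both WT libraries and an average of at least 1 RPM. RPM is reads per 1e6 of the library total. Predicted gene symbols were left out there, and list members were held to none of these conditions. Where none passed it took the 3 with the smallest p, said not to pass. For the interaction it took up to 5 per direction, leaving out predicted symbols alone. Krtap19-9a was so named at an untreated average of 0.388 RPM. After the data were examined, the 6 higher and 6 lower genes with the smallest p in the deposited tables were added by the same exclusions. List members outside this rule are named as examples chosen after their values were seen.

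The size of the untreated genotype effect kept under 5-aza was read from 200 genes. They were picked in 1 WT and 1 DKO untreated library and read in the other pair, over 4 splits. They had at least 5 RPM on average over all 8 libraries. Overlaps were tested by Fisher's exact test, which treats genes as independent units. The alternatives were other filters, scalings, pseudocounts of 0.1 and 5, a robust fit, a replicate block, a fold minimum of 2, leaving out each library, all 8 libraries in 1 fit, voom on whole reads, no variance trend and protein-coding genes alone. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the tables and plots. The zero floor was 3 reads; floors cover counting error only. Gene positions are those of the deposited tables on GRCm38.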

Results

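RNA was measured in hair matrix keratinocytes, the dividing epithelial cells at the base of the hair follicle that give rise to the hair shaft and the inner root sheath. The mice were labelled wild type (WT) or double knockout (DKO) for Tet2 and Tet3, which encode dioxygenases that oxidise 5-methylcytosine in DNA. They were untreated or had received 5-aza, an inhibitor of DNA methyltransferases. Each of the 4 groups had 2 libraries. Library totals ranged from 19528602 to 22837436 reads in the untreated groups and from 39493929 to 58353167 reads in the 5-aza groups. These totals are not alike, since the authors list reads not aligned, or aligned with low quality, for the 5-aza libraries alone. Listed genes held 11825515 to 14132115 reads in the untreated libraries and 16744915 to 23512270 in the 5-aza libraries. Values are given in FPKM as mean ± SD with n = 2 libraries per group, and log2 differences are of log2(FPKM + 1), DKO minus WT, ± SE. Whether the libraries came from separate animals is not stated, so the p-values of single genes measure only the spread between these libraries. Those of camera and of Fisher's exact test also rest on comparisons across genes.

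Tet3 (ENSMUSG00000034832, chromosome 6, 83362373 to 83459084) was 11.6 ± 0.312 FPKM in untreated WT and 7.11 ± 0.279 FPKM in untreated DKO. Its level fell by 0.63 ± 0.09 on the log2 scale adjusted over the list alone (adjusted p = 0.023 among genes of the DNA methylation machinery, 0.151 over all genes, limma). After 5-aza, Tet3 was 10.9 ± 0.773 FPKM in WT and 6.27 ± 0.386 FPKM in DKO, and fell by 0.72 adjusted over the list alone (adjusted p = 0.017, 0.308 over all genes). Tet2 (ENSMUSG00000040943, chromosome 3, 133463679 to 133545139) was 3.25 ± 0.0343 FPKM in untreated WT and 2.63 ± 0.120 FPKM in untreated DKO (adjusted p = 0.432). Its values after 5-aza were 1.90 ± 0.130 and 1.57 ± 0.0164 FPKM (adjusted p = 0.583). These gene-level values do not show the loss of either gene: DKO over WT was 0.614 and 0.573 for Tet3 and 0.809 and 0.826 for Tet2, and no value inside a deleted part was analysed here. In the authors' deposited table the untreated log2 difference of Tet3 was -0.73 and that of Tet2 was -0.33, with adjusted p of 1.8e-07 and 0.30.

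The first comparison asked which genes differed between DKO and WT matrix keratinocytes without treatment. Krt28, a keratin of the inner root sheath, was 70.5 ± 0.231 FPKM in WT and 2.42 ± 0.618 FPKM in DKO, 29.2-fold lower. It fell by 4.40 ± 0.15 on the log2 scale and was the 1 gene of 17339 past the threshold (adjusted p = 0.0235, limma). Hair shaft keratins and keratin-associated proteins, the structural proteins of the hair fibre, were higher in DKO as lists with the preset correlation, but not with an estimated one (adjusted p = 0.362 with an estimated correlation for each). Krt34 was 11.7-fold and Krtap8-1 8.92-fold higher, and neither passed over all genes (adjusted p = 0.0831 and 0.105). Dermal papilla markers were lower as a list with the preset correlation and with fry (adjusted p = 0.0333), but not with an estimated correlation (adjusted p = 0.362 with an estimated correlation). Of these, Corin was 13.6 ± 0.048 FPKM in WT and 6.02 ± 0.471 FPKM in DKO and did not pass over all genes (adjusted p = 0.0831). Krt28 (ENSMUSG00000055937) lies on the minus strand of chromosome 11, from 99364872 to 99374903, and is annotated as protein-coding. The higher genes with the smallest p, Dio3os, Serpinb3b and Krtap3-3, did not pass (adjusted p = 0.0606 each). At an unadjusted p under 0.05, 1165 genes were higher and 821 lower in DKO; these were 1085 and 1013 with scaling to reads in genes. Without WT replicates 1 and 2 and DKO replicates 1 and 2 in turn, they were 1047 and 1001, 1623 and 955, 930 and 521, and 538 and 395. The authors' deposited table lists 379 genes with an adjusted p under 0.05, 235 higher and 144 lower in DKO. In the authors' deposited table the smallest p by the naming rule belonged to Krt16, Krt33b, Krt83, Krtap8-1, Krt31 and Krt34, higher in DKO, and to Krt28, Gfra1, Dio2, Corin, Hist1h2bn and P2rx7, lower. Dio2, a deiodinase that activates thyroid hormone, was 16.3 ± 0.293 FPKM in WT and 4.06 ± 0.435 FPKM in DKO. The Krt28 call ended when any 1 untreated library was left out (adjusted p from 0.0998 to 0.274). It also ended without a filter (0.264), with a filter of 0.1 FPKM (0.189) and without the variance trend (0.0712), and the number of genes called ranged from 0 in these settings to 77 with voom and 182 with all 8 libraries in 1 fit.

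Hair shaft keratins rose as a list in untreated DKO, with a median log2 difference of 2.49 over 14 measured members (camera adjusted p = 1.0e-16). This call was lost with an estimated correlation (adjusted p = 0.362 with an estimated correlation). All 14 members had positive differences, 12 rose adjusted over the list alone, and 0 passed over all genes with limma. Krt31 was 5.66 ± 1.39 FPKM in WT and 46.5 ± 14.0 FPKM in DKO, and Krt81 was 2.58 ± 1.14 and 30.2 ± 6.44 FPKM. Krt34 was 1.41 ± 0.409 and 16.4 ± 4.75 FPKM. Keratin-associated proteins rose as a list, with a median of 1.75 over 22 members (adjusted p = 4.7e-25 preset, adjusted p = 0.362 with an estimated correlation). Of these, 21 rose adjusted over the list alone and 0 passed over all genes. Krtap8-1 was 9.26 ± 3.91 FPKM in WT and 82.6 ± 17.0 FPKM in DKO, and Krtap3-3 was 0.537 ± 0.0852 and 3.88 ± 0.122 FPKM. The list's median was 0.24 when every keratin-associated protein gene with a read was kept. In the authors' deposited table, 10 of 15 listed hair shaft keratins and 14 of 52 keratin-associated proteins were higher, and 0 were lower.

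**Figure D1:**
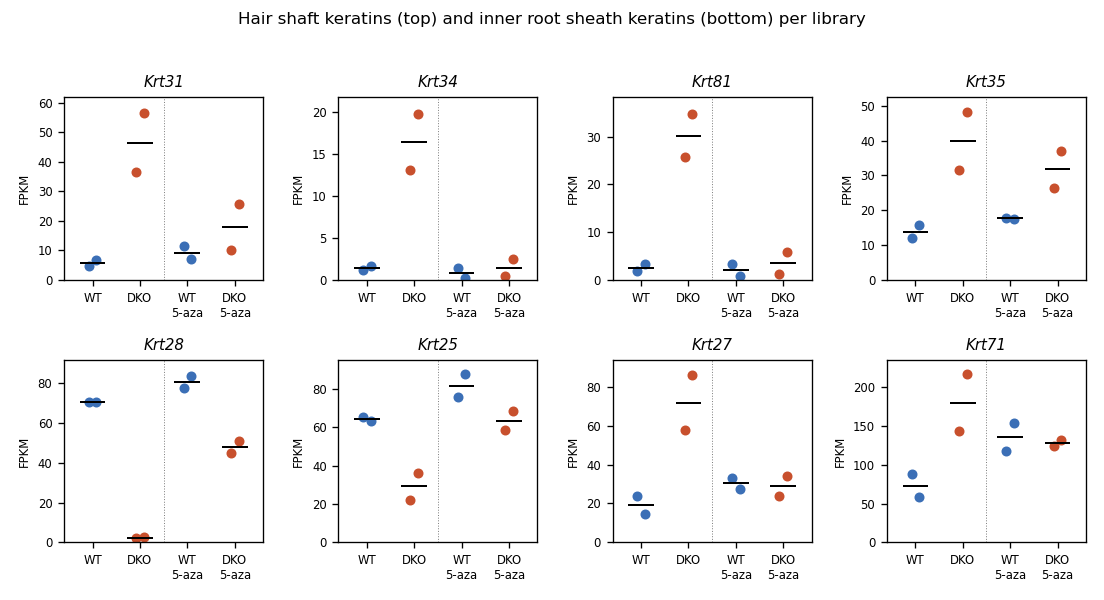
FPKM of 4 hair shaft keratins and 4 inner root sheath keratins in each group, with points for the 2 libraries and a line at their mean. Krt28 averaged 70.5 FPKM in untreated WT and 2.42 in untreated DKO, and 80.6 and 48.1 after 5-aza.

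Inner root sheath genes moved both ways in untreated DKO. Adjusted over the list alone, 7 of 19 rose and 4 fell; over all genes 1 fell, Krt28. Krt27 was 71.8 ± 20.1 FPKM in DKO, 3.76-fold above WT, and Tchh, which encodes trichohyalin, was 5.85 ± 1.33 and 26.2 ± 11.6 FPKM. Krt71 was 73.3 ± 21.4 and 180.2 ± 51.9 FPKM. Krt25, of the same keratin cluster as Krt28, was 64.0 ± 1.46 and 29.2 ± 9.71 FPKM. Dsg4, a desmosomal cadherin of the hair follicle, was 3.52 ± 0.292 and 13.9 ± 2.29 FPKM. The list had no shift in one direction past the threshold (camera adjusted p = 0.418), while fry's test for changes in either direction gave an adjusted p of 0.00287.

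Basal and outer root sheath genes rose as a list in untreated DKO (median 0.28, 24 members, adjusted p = 2.3e-05 preset, adjusted p = 0.427 with an estimated correlation). Adjusted over the list alone 4 rose, Krt16, Krt15, Krt6a and Krt14, and 0 passed over all genes. Krt16, a keratin induced in activated epidermis, was 2.01 ± 0.415 FPKM in WT and 21.6 ± 5.29 FPKM in DKO. Hair matrix and shaft regulators rose by a median of 0.11 over 30 members (adjusted p = 0.0120 preset, 0.427 with an estimated correlation). Foxn1, a transcription factor needed for hair shaft differentiation, was 3.52 ± 0.284 and 7.59 ± 0.721 FPKM, and rose adjusted over the list alone, as did Ovol1, Wnt10a and Bmp2. Wnt pathway genes rose by a median of 0.17 over 30 members (adjusted p = 0.0078 preset, 0.589 with an estimated correlation), with Wnt3a, Fzd5 and Wnt10a past the threshold adjusted over the list alone. Notch pathway genes rose by a median of 0.16 (adjusted p = 0.0180 preset, 0.427 with an estimated correlation) with 0 of 18 members past the threshold adjusted over the list alone.

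DNA methylation machinery genes fell in untreated DKO (median -0.06, adjusted p = 0.0186 preset, 0.427 with an estimated correlation), with Tet3 the 1 of 24 past the threshold adjusted over the list alone. This list holds Tet2 and Tet3, the genes that the DKO label names, and was not tested without them. The median was 0.0073 in the pair of replicates 1, with 13 of 24 positive, and -0.13 in the pair of replicates 2, with 6 positive. Hox genes fell (median -0.10, 28 members, adjusted p = 0.0108 preset, 0.362 with an estimated correlation). Hoxc9 was 0.964 ± 0.0635 FPKM in WT and 0.361 ± 0.0441 FPKM in DKO, and Hoxc6 was 4.17 ± 0.137 and 2.61 ± 0.0905 FPKM; both fell adjusted over the list alone. No shift passed for interfollicular differentiation genes (adjusted p = 0.753), the BMP pathway (0.126), the Hedgehog pathway (0.842), proliferation (0.177), p53 targets (0.108), interferon-stimulated genes (0.803), germline genes (0.0969) or imprinted genes (0.0581). Piwil2, a germline Argonaute gene, was 0.960 ± 0.425 and 0.151 ± 0.00854 FPKM and fell adjusted over the list alone. Hist1h2bn was 150.7 ± 14.5 FPKM in WT and 20.8 ± 4.12 FPKM in DKO and fell adjusted over the list alone among 64 histone genes, whose list did not shift (adjusted p = 0.266).

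Markers of other cell types also differed between the untreated genotypes. Dermal papilla markers fell (median -0.55, 16 members, adjusted p = 6.1e-08 preset, adjusted p = 0.362 with an estimated correlation, 0.0333 with fry), and 7 fell adjusted over the list alone, among them Corin, Inhba and Rspo3, with 0 over all genes. Hhip, Notum and Prdm1 of that list also stand in the Hedgehog, Wnt and regulator lists. Immune markers rose (median 0.27, 16 members, adjusted p = 1.1e-06 preset, 0.362 with an estimated correlation), with 8 higher and 1 lower adjusted over the list alone. Cd74 was 1.76 ± 0.490 FPKM in WT and 5.99 ± 1.23 FPKM in DKO. Endothelial and mural markers rose by a median of 0.17 (adjusted p = 2.9e-05 preset, 0.362 with an estimated correlation), and adipocyte markers by 0.30 (0.000127 preset, 0.362 with an estimated correlation, 0.0333 with fry; 4 of 5 adjusted over the list alone). Melanocyte markers rose by 0.14 (0.0412 preset, 0.427 with an estimated correlation). Muscle markers passed with fry alone, higher in DKO (median 0.04, adjusted p = 0.0333 with fry, 0.0969 preset, 0.427 with an estimated correlation). No shift passed for fibroblast (0.579), erythroid (0.177), or Schwann and Merkel markers (0.619), though S100b fell adjusted over the list alone. Among quality lists, ribosomal protein genes rose by 0.17 (0.00136 preset, 0.795 with an estimated correlation), and dissociation stress genes (0.0511) and sex-linked genes (0.838) did not pass. The median, the mean and the camera direction differed in sign for the Hedgehog, interferon, Schwann and Merkel, histone and sex-linked lists.

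Xist, the RNA that coats the inactive X chromosome, was 82.1 FPKM in untreated WT replicate 1 and 74.4 FPKM in DKO replicate 1, and 0.327 and 1.19 FPKM in replicates 2. Ddx3y, on the Y chromosome, was 0.0155 and 0.0755 FPKM in replicates 1 and 3.50 and 2.90 FPKM in replicates 2. With the replicate number as a block, 13 untreated genes passed, 12 higher and 1 lower in DKO. Within the pair of replicates 1 and the pair of replicates 2, the median differences were 2.44 and 2.54 for hair shaft keratins, 1.67 and 1.88 for keratin-associated proteins, and -0.61 and -0.45 for dermal papilla markers. Fibroblast markers gave 0.65 and -0.33, interfollicular differentiation genes -0.81 and 0.57, and immune markers 0.45 and 0.15. Melanocyte markers gave 0.16 and 0.02.

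The second comparison asked which genes differed between DKO and WT after 5-aza. Basal and outer root sheath genes were higher in DKO as a list with the preset correlation only (adjusted p = 0.866 with an estimated correlation). Krt14, a keratin of basal keratinocytes, was 36.3 ± 9.57 FPKM in WT and 83.1 ± 17.0 FPKM in DKO and did not pass over all genes (adjusted p = 0.388). H19, an imprinted noncoding RNA, was 9.15 ± 0.354 and 22.4 ± 1.22 FPKM. Krt28 was 80.6 ± 4.16 and 48.1 ± 4.23 FPKM, and Piwil2 was 5.12 ± 0.695 and 1.48 ± 0.0940 FPKM. With limma, 0 of 16856 genes passed over all genes, and 1507 had an unadjusted p under 0.05, 1120 higher and 387 lower. With median-ratio scaling these were 820 and 589, and with scaling to reads in genes 741 and 707. Leaving out WT replicates 1 and 2 and DKO replicates 1 and 2 in turn gave 819 and 389, 588 and 461, 725 and 266, and 890 and 334. Voom also called 0 genes, and the authors' deposited table lists 207, 160 higher and 47 lower in DKO. The genes with the smallest p did not pass: Hspb8, Calm4 and H19 were higher and Lbh, Gnmt and Piwil2 lower (adjusted p from 0.209 to 0.274). With WT replicate 1 paired with DKO replicate 2 and WT replicate 2 with DKO replicate 1, a pairing chosen after the data were seen, 91 genes passed, 57 higher and 34 lower.

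Basal and outer root sheath genes rose as a list after 5-aza (median 0.40, 23 members, adjusted p = 1.4e-08 preset, adjusted p = 0.866 with an estimated correlation). Adjusted over the list alone 12 rose, among them the laminin genes Lama3 and Lamb3, and 0 passed over all genes. Lama3 was 3.11 ± 0.0578 FPKM in WT and 5.03 ± 0.225 FPKM in DKO. Interfollicular differentiation genes rose by a median of 0.34 over 20 members (adjusted p = 4.0e-06 preset, 0.866 with an estimated correlation), 5 of them adjusted over the list alone. Lor, which encodes loricrin of the cornified envelope, was 0.375 ± 0.0607 and 1.13 ± 0.00188 FPKM. Regulators rose by 0.20 (0.0217 preset, 0.866 with an estimated correlation), with Hoxc13, Runx1 and Ovol1 past the threshold adjusted over the list alone. Hoxc13, a regulator of hair keratin genes, was 12.3 ± 0.963 and 22.6 ± 0.774 FPKM. Wnt (median 0.15, adjusted p = 0.0496), BMP (0.13, 0.00239) and Notch (0.12, 0.0347) lists and interferon-stimulated genes (0.06, 0.0164) rose with the preset correlation. Each had an adjusted p of 0.866 with an estimated correlation and 0 members past the threshold adjusted over the list alone. The interferon list's median was 0.03 without DKO replicate 2, where its camera direction turned.

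Replication-dependent histone genes fell after 5-aza (median -0.31, adjusted p = 3.3e-20 preset, adjusted p = 0.866 with an estimated correlation), with negative differences in 58 of 61 members and 0 past the threshold adjusted over the list alone. Proliferation genes fell by 0.06 (adjusted p = 0.000866 preset, 0.866 with an estimated correlation), but the list's median was 0.04 without DKO replicate 2. Germline genes (median -0.02) and Hox genes (median -0.05) fell, each with an adjusted p of 0.0455 preset and 0.866 with an estimated correlation. In WT replicate 1 with DKO replicate 2 the median was -0.11 for proliferation and -0.04 for germline genes (5 of 22 positive), and in the other crossed pair 0.0041 and 0.0095 (12 of 22 positive). Piwil2 fell and H19 and Hoxc13 rose adjusted over their lists alone. Hair shaft keratins had a median of 0.36 and did not pass (adjusted p = 0.396), nor did keratin-associated proteins (0.853) or inner root sheath genes (0.0744). Of the last, Dsg4 and Krt26 rose and Krt28 fell adjusted over the list alone. The Hedgehog pathway (0.103), p53 targets (0.113), imprinted genes (0.159) and DNA methylation machinery (0.982) did not pass. The median, the mean and the camera direction differed in sign for the keratin-associated protein, p53, imprinted, methylation machinery, adipocyte, mitochondrial and sex-linked lists.

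Dermal papilla markers fell after 5-aza (median -0.39, adjusted p = 0.000866 preset, adjusted p = 0.866 with an estimated correlation), with 0 of 16 adjusted over the list alone. Ribosomal protein genes rose by 0.16 (7.3e-05 preset, 0.866 with an estimated correlation). The sex-linked list passed with the preset correlation (0.0301, 0.866 with an estimated correlation): Xist was 20.0 ± 4.38 FPKM in WT and 4.13 ± 0.668 FPKM in DKO, and the Y-linked members rose adjusted over the list alone. Unlike the untreated libraries, each 5-aza library held both: Xist was 16.9 and 23.1 FPKM in WT and 4.60 and 3.65 FPKM in DKO, and Ddx3y was 1.24 and 0.917 FPKM in WT and 2.08 and 2.00 FPKM in DKO. The balance of X- and Y-linked markers of sex thus differed between the 5-aza genotype groups, and the sex of the animals is not stated. A difference in sex cannot be told apart from genotype in the 5-aza comparison. No shift passed for melanocyte (0.853), fibroblast (0.436), endothelial and mural (0.678), immune (0.594), adipocyte (0.675), muscle (0.396), or Schwann and Merkel markers (0.159), nor for stress (0.283) or mitochondrial genes (0.624). Melanocyte markers differed within genotypes: Pmel, a melanosome protein gene, was 36.9 and 7.06 FPKM in WT replicates 1 and 2 and 9.07 and 55.1 FPKM in DKO replicates 1 and 2. All 14 melanocyte markers were higher in WT replicate 1 and DKO replicate 2 than in both other 5-aza libraries, as were 11 of 14 hair shaft keratins, 9 dermal papilla markers and 14 fibroblast markers. Quality lists moved with this split: 17 of 22 dissociation stress genes were higher in the same way (median 0.35), and 0 of 10 mitochondrially encoded genes (median -0.63). In the pairs of libraries alike in these markers, the median differences were 0.42 and 0.51 for basal and outer root sheath genes, 0.51 and 0.21 for hair shaft keratins, and -0.35 and -0.27 for histone genes.

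**Figure D2:**
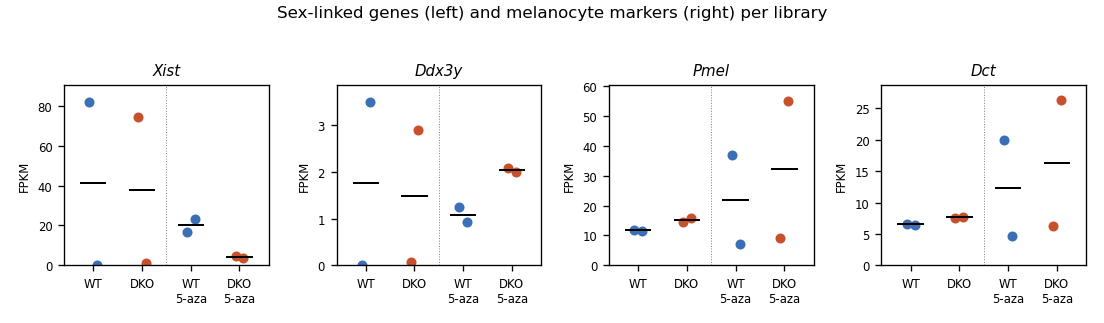
FPKM of Xist, Ddx3y, Pmel and Dct in each group, with points for the 2 libraries and a line at their mean. Pmel was 36.9 and 55.1 FPKM in 1 library of each 5-aza genotype and 7.06 and 9.07 FPKM in the other.

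The third comparison asked whether the genotype difference itself differed between untreated and 5-aza libraries. The genotype difference of Krt28 was 3.67 ± 0.20 higher on the log2 scale after 5-aza than without treatment (adjusted p = 0.00787, limma). The difference of Krtap3-3 was lower after 5-aza, with -1.62 ± 0.13 (adjusted p = 0.0436); it was 0.367 ± 0.111 FPKM in WT and 0.417 ± 0.103 FPKM in DKO after 5-aza. Serpinb3b, a serine protease inhibitor gene, and Dio3os, a noncoding RNA beside Dio3, had interaction values of -1.22 ± 0.06 and -0.999 ± 0.08 (adjusted p = 0.00787 and 0.0436). Dio3os was 0.0298 FPKM in WT and 1.46 FPKM in DKO untreated, and 0.00732 and 0.204 FPKM after 5-aza. Its mean was thus higher in DKO in both, at a lower level after 5-aza. Krtap19-9a, annotated as a processed pseudogene, had -2.42 ± 0.20 (adjusted p = 0.0436); it was listed at 0 in WT in both tables, and Serpinb3b at 0 in both 5-aza WT libraries. The values of all 4 lower genes depend on the pseudocount: with 0.1 and 5 they were -2.54 and -0.39 for Serpinb3b, -2.12 and -0.30 for Dio3os, -2.50 and -0.67 for Krtap3-3, and -5.05 and -0.94 for Krtap19-9a. None of the 4 passed with 0.1 (adjusted p from 0.124 to 0.579) or with voom (0.986 each). No gene passed with the replicate block or with crossed pairs as a block, where Krt28 and Serpinb3b each had an adjusted p of 0.263 and 0.107. Of 18505 genes, 5 passed, 1 higher and 4 lower, and 1126 had an unadjusted p under 0.05, from 716 without DKO 5-aza replicate 1 to 1829 without WT untreated replicate 2. No gene passed when any 1 of the 5-aza libraries was left out (adjusted p of Krt28 from 0.0701 to 0.105), and 8 passed without WT untreated replicate 2 and 11 without DKO untreated replicate 1; Dio3os and Krtap3-3 did not pass without any 1 of the 8 libraries (adjusted p of at least 0.0647 and 0.0588). The tables were processed separately, so a difference between them that acts on WT and DKO unequally stays in these values. In genes of low FPKM one common to both also stays, through the pseudocount. Xist and Ddx3y were alike between the untreated genotypes by replicate number but differed between the 5-aza genotypes. A difference in sex thus cannot be told apart from 5-aza in these values.

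Hair shaft keratins had a lower genotype difference after 5-aza (median -1.98, 14 members, adjusted p = 1.5e-10 preset, adjusted p = 0.517 with an estimated correlation), with 9 lower adjusted over the list alone and 0 over all genes. Keratin-associated proteins did too (median -1.68, 23 members, adjusted p = 1.9e-33 preset, adjusted p = 0.146 with an estimated correlation), with 21 lower adjusted over the list alone and 2 over all genes. Of 19 inner root sheath genes, Krt28 and Krt26 were higher and Krt27 lower adjusted over the list alone. Immune (median -0.21), endothelial and mural (-0.16) and adipocyte markers (-0.29) and p53 targets (-0.08) were lower, with preset adjusted p of 3.2e-08, 2.5e-06, 4.5e-06 and 0.00284, and an adjusted p of 0.146 with an estimated correlation for each. In the 5-aza comparison alone, 12 keratin-associated proteins and 5 immune markers passed the filter, against 23 and 17 here. For members near 0 FPKM after 5-aza, the interaction largely repeats the untreated difference with its sign reversed. The shifts of these lists are thus no separate evidence of a response to 5-aza. Histone genes were lower (median -0.23, 2.8e-05 preset, 0.691 with an estimated correlation) and DNA methylation machinery genes higher (median 0.07, 0.0203 preset, 0.550 with an estimated correlation). Dermal papilla markers (median 0.03, adjusted p = 0.811) and basal and outer root sheath genes (median 0.09, adjusted p = 0.780) did not pass.

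**Figure D3:**
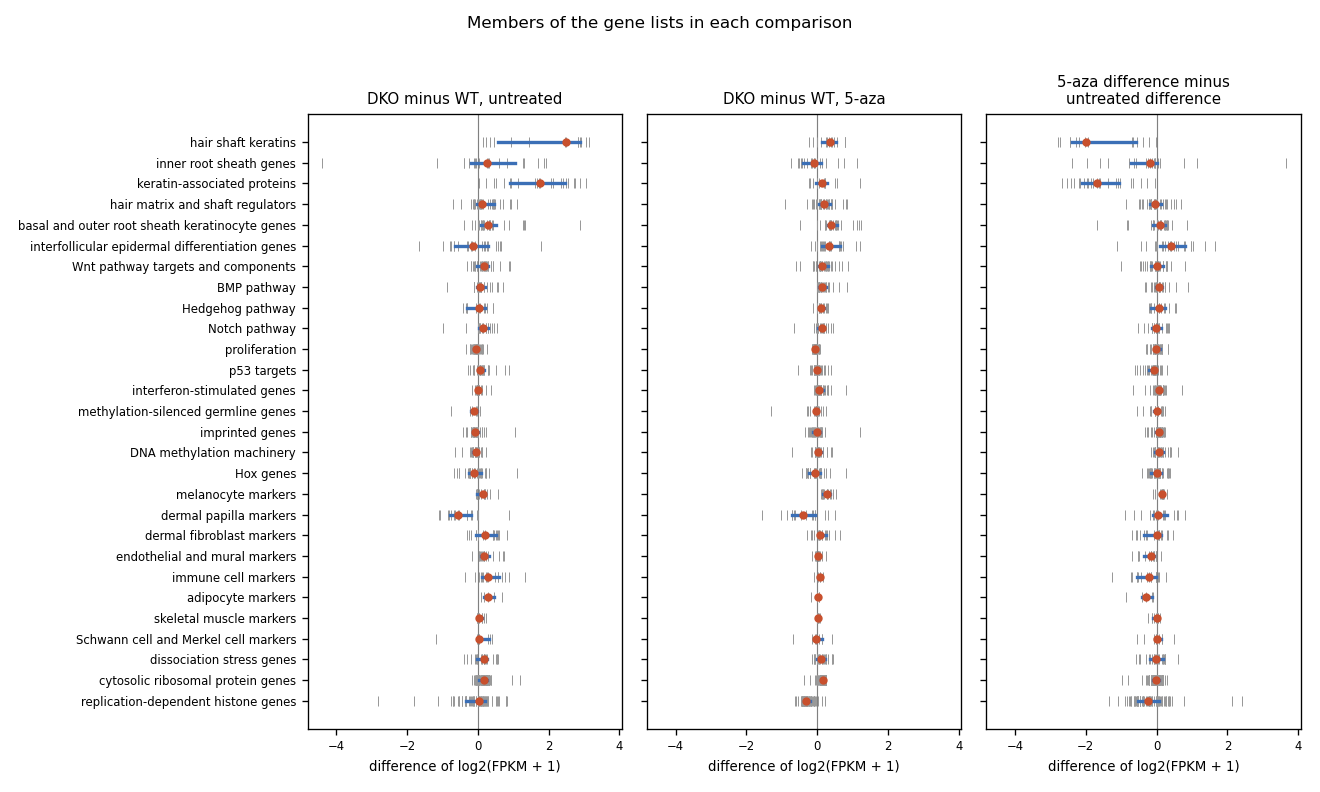
Difference of log2(FPKM + 1) of the members of each list in the 3 comparisons, with a tick per gene, a bar from the lower to the upper quartile and a point at the median. Hair shaft keratins have medians of 2.49 untreated, 0.36 after 5-aza and -1.98 in the interaction.

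The last comparison asked how much of the untreated genotype difference was seen after 5-aza. For 200 genes picked in 1 untreated pair of libraries, the slope was 0.525 in the other untreated pair (0.434 to 0.595 over 4 splits) and 0.225 in the 5-aza comparison (0.170 to 0.257). The 5-aza difference had the sign of the picked one in 85.1% of genes, and the other untreated pair in 80.1%. These values are not alike in noise, since the 5-aza difference averaged 4 libraries and the other untreated pair held 1 of each genotype. They are also not alike in level. Of 26200 shared genes, 12272 were lower in every 5-aza library than in every untreated one. At low FPKM the pseudocount shrinks a log2 difference. How far this lowered the 5-aza slope was not tested. In splits that crossed the replicate numbers, the picked and the other pair set Xist-high against Ddx3y-high libraries in opposite directions. The effect of this was not tested. The 5-aza genotypes also differed in Xist and Ddx3y, so sex and genotype cannot be told apart in the 5-aza slope. Across 15699 genes tested in both, which are not independent replicates, the differences had a Pearson correlation of 0.453 and a Spearman correlation of 0.380. With limma, 0 genes passed in both comparisons. At an unadjusted p under 0.01, 76 genes were higher in both (5.92 expected, Fisher's exact p = 1.4e-63), 14 lower in both (0.845 expected, p = 8.7e-14) and 1 opposite. In the authors' deposited tables, 52 genes were higher in both and 13 lower in both, with 0 opposite. The shared genes of the authors' deposited tables include Krt14, Krt16, Krt35, Dsg4, Hoxc13 and H19, higher in DKO, and Krt28, Tet3 and Piwil2, lower.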

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

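The test on other hair shaft genes and the test on a lower keratinocyte share were set before their results were seen; the reading of the latter without a pseudocount and the other tests here were chosen after the results were seen.

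The genotype differences of 5 genes differed between untreated and 5-aza libraries by the interaction test. The values were 3.67 for Krt28, -1.22 for Serpinb3b, -0.999 for Dio3os, -1.62 for Krtap3-3 and -2.42 for Krtap19-9a, all on the log2 scale. None of the 5 passed with either block, and the last 4 depend on the pseudocount. The mean of Dio3os was still higher in DKO after 5-aza, with 0.00732 FPKM in WT and 0.204 FPKM in DKO.

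Krt28 was lower in untreated DKO. Fewer inner root sheath cells would lower its partners too, but Krt25, Krt27, Krt71, Krt73 and Tchh had a median log2 difference of 1.32, although Krt25 was lower. A sequence variant of all DKO animals that keeps reads from Krt28 is argued against by the 5-aza libraries with the same genotype label. There DKO over WT was 0.598. A variant that only some DKO animals carry stays open. Each 5-aza library held both Xist and Ddx3y and may mix animals, so this ratio cannot decide on it. Reads moved to Krt25, Krt26 and Krt27 would keep the sum of the 4 genes, but its ratio was 0.635. The sum was 137 to 211 RPM in DKO and 265 to 283 in WT, which argues against such a move as the whole cause. A part stays open, since Krt25 fell and Krt27 rose, which the sum does not separate. A change that follows the genotype stays open as a hypothesis, found and tested on the same libraries.

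Hair shaft keratins and keratin-associated proteins were higher in untreated DKO. Scaling is argued against for the hair shaft keratins, since the lower of that list's medians under other scalings was 2.46. No such value is given here for the keratin-associated proteins. Reads moved between keratin copies are argued against as the whole cause, since the summed reads of the 2 families had DKO over WT ratios of at least 5.90. For reads shared between copies, 8 other hair shaft genes had a median difference of 1.21. That lay above the 0.5 that sharing allows by more than their largest standard error of 0.304. It lay above the bound of 1 set before by less, so this test missed its bound and does not decide on sharing. A larger share of hair shaft cells in the DKO sorts stays open: the highest DKO over WT ratio was 8.16 times the lowest, over the bound of 2 for a common factor, but other cells that make some of these keratins, or stages of the lineage, could spread the ratios. A change per cell and a change in the cells sorted cannot be told apart here.

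After 5-aza, WT replicate 1 and DKO replicate 2 had higher melanocyte markers than the other libraries, with 17 of 22 dissociation stress genes higher and median ratios of mitochondrially encoded genes of 0.650 and 0.497. Depth is argued against, since the library totals had ratios of 1.03 in WT and 1.48 in DKO and the markers median ratios of 4.58 and 5.01. A lower share of keratinocytes would raise every other cell type alike and is argued against as the whole cause. The median log2 ratio was 2.25 for melanocyte markers, 1.14 above that of fibroblast markers, and 0.71 for endothelial and mural markers. With the pseudocount, the medians of these lists were 1.41, 0.58 and 0.05. Of 14 hair shaft keratins, 14 were higher within each genotype too, and 11 were above both other libraries. A lower keratinocyte share stays open for a part of the split. Dermal papilla, fibroblast, adipocyte, and Schwann and Merkel markers had like ratios (1.07, 1.12, 0.97 and 0.93). A larger share of melanocytes and a difference in handling or RNA quality also stay open and were not tested. No biological explanation was tested, since the design names no group along this split.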

How the results depend on the processing

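The tests with voom, without a variance trend, with the 0.1 FPKM filter, with scaling to reads in genes, on protein-coding genes and with crossed pairs, and the overlap of the deposited calls, were chosen after the data were seen. Untreated genes past the threshold were 1 and became 0 without a filter, without the variance trend and with the 0.1 FPKM filter, 30 with a filter of 1 RPM, 13 with a replicate block, 8 with a pseudocount of 0.1, 182 with all 8 libraries in 1 fit, 77 with voom and 72 with protein-coding genes alone. Leaving out each library gave 0 in every case. After 5-aza the count with limma was 0 (1507 at an unadjusted p under 0.05), 1 with all 8 libraries in 1 fit, 91 with crossed pairs, and 0 with voom and without each library. For the interaction the count was 5 and became 2 with median-ratio scaling, without a filter, with a robust fit, without the variance trend, with the 0.1 FPKM filter and with scaling to reads in genes, 1 with a pseudocount of 0.1 and with voom, and 0 with the replicate block and with crossed pairs. It ranged from 0 to 11 without each library. Shared calls were 0 and became 90 at an unadjusted p under 0.01, 129 with voom at that p and 65 in the deposited tables. Lists past the threshold were 14 untreated, 14 after 5-aza and 8 for the interaction. With an estimated correlation they were 0, 0 and 0, and with fry 3, 0 and 0. Leaving out each library gave 12 to 17, 9 to 17 and 7 to 14, the 9 without WT 5-aza replicate 2 and the 14 without DKO 5-aza replicate 1. Of these lists, 14, 12 and 8 kept their direction in every alternative run, and 8, 4 and 3 stayed past the threshold in all but the estimated correlation and fry. Directions turned on leaving out a library (for the interferon list that of camera, not of the median), over which the median was -0.16 to 0.0422 for proliferation and 0.0250 to 0.13 for interferon-stimulated genes after 5-aza. Untreated, the ranges were -0.27 to 0.23 for Hspa8, -0.47 to 0.82 for Acta2, -2.17 to 0.73 for Hbb-bs and -2.69 to 3.27 for Xist. After 5-aza they were -0.22 to 0.51 for Sox10 and -1.31 to 0.0665 for Hbb-bs. Of the 71 genes that the naming rule and its addition took untreated, 65 kept their sign, of 73 after 5-aza 66, and of 5 for the interaction 5. The slope kept after 5-aza was 0.199 for 100 genes, 0.247 for 500 and 0.186 from 1 RPM. The cause of these changes was not tested, except that fewer libraries or genes change the number of tests and the spread. When a group is left with 1 library, that library is assumed to vary like the others. Whether the replicate numbers pair the libraries is not stated. The residuals of libraries of the same number had a correlation across genes of 0.03 untreated and -0.589 after 5-aza, but in both untreated genotypes Xist was high in replicate 1 and Ddx3y in replicate 2. Count models were not run because the plan took its fallback where the columns are not counts. Whole reads were recovered from the FPKM, so such models could have been fitted, and voom on these reads called 77 untreated genes. Library totals alone are the scaling already used. With 2 libraries per group, the test called 36.6% of simulated 2-fold changes in untreated data and 46.6% in 5-aza data. This does not show what the real data could detect, since Krt81 and Krt34, each 11.7-fold higher in untreated DKO, did not pass (adjusted p = 0.0831 each).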

Other observations

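The following values were chosen after the data were seen and come from tables processed separately, so they were not tested. Of 24 genes of the methylation-silenced germline list that both tables hold, 13 had every 5-aza library above every untreated library (54.2%) and 3 had every 5-aza library below. Not all were silent untreated, since Syce2 was 2.77 to 4.35 FPKM there. Of all 26200 shared genes, 918 (3.5%) lay above in this way and 12272 below. Tuba3b was 0.0495 FPKM in WT replicate 1 and 0 in the other untreated libraries, and 4.67 to 6.23 FPKM in the 5-aza libraries. Tex19.1 was at most 0.167 FPKM untreated and 0.991 to 1.97 FPKM after 5-aza. Taf7l was listed only in the 5-aza table, at 0.793 to 1.12 FPKM. Some interfollicular differentiation genes went the other way. Krt1 was 42.6 to 110.3 FPKM untreated and 0.171 to 1.61 FPKM after 5-aza, and Krt10 was 63.4 to 173.9 and 0.703 to 4.87 FPKM. Other members overlapped, such as Lgals7 at 63.1 to 85.0 and 63.9 to 78.8 FPKM. A difference in the cells sorted or in the processing thus cannot be told apart from 5-aza in these levels.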
